A study of Mus musculus with 6 samples.

How the data were processed

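RNA was measured in 6 libraries of mouse peritoneal macrophages, 3 from wild-type (WT) mice and 3 from mice in which Fbxo38 was deleted in myeloid cells (conditional knockout, cKO). The cells had been stimulated with IL-4 and IL-13 at 20 ng/mL for 24 h. Per the labels' protocols, RNA with poly(A) tails was selected, libraries were made with a stranded kit, and fragments were read from both ends on a NovaSeq sequencer. Reads were trimmed with fastp, aligned with HISAT2 in a strand-aware mode and assembled against a reference with StringTie, per the labels' protocols. RSEM and DESeq2 are named, without versions, per the submitters' processing notes. The genome build and the annotation are not given in the sources used here, so no coordinates are printed.

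The deposited main table gives 1 row per transcript, not per gene. Its values per library are TPM (transcripts per 1000000 transcripts), as the authors computed them over all transcripts of a library. The authors also deposited a fold change of cKO over WT as a ratio, its log2 value, a p-value and an adjusted p-value. Columns were assigned to libraries by their labels, and 0 columns of per-sample values could not be matched. The table holds 33539 transcripts of 16358 genes, 31854 with a reference identifier and 1685 assembled by StringTie. Each listed transcript has an absolute deposited log2 fold change of at least 1.0001, so the table was selected on the outcome. The listed transcripts hold between 2.01% and 6.57% of the 1000000 TPM of a library. The ratio of the deposited p-values to their adjusted values fits an adjustment over about 39400 transcripts. Transcripts outside the table were not analysed here. TPM keeps no read depth, so the depth per library is unknown and no counting interval is given. The selection of the table means that p-values computed on it run over transcripts already chosen for a difference between the groups, and they are smaller than in an unselected set.

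The planned tests assumed genes. They were run on transcripts because the table lists transcripts. A transcript was tested if its TPM was at least 1 in at least 3 of the 6 libraries, which left 2050 transcripts of 1758 genes. Values were transformed as log2(TPM + 1), and WT and cKO were compared with limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean, group as the only term, two-sided tests and Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of low transcripts. For Fbxo38, the TPM of its listed transcripts were also summed per library and tested as 1 further row that entered no count. Exact permutation tests of single values are two-sided, and with 3 libraries against 3 they give no p below 0.1. The 3 libraries of a group are separate samples per the labels, which speak of pairs of littermates but do not say which numbers form a pair.

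For 37 gene lists fixed before the data were examined, the 20 with at least 5 tested transcripts were compared with all other tested transcripts by camera, with a preset correlation of 0.01. Camera with a correlation estimated from the data and fry were run beside it. A list counts each transcript of a gene separately. Genes to be named were set by a rule fixed at the same time. The rule takes Fbxo38. It takes up to 10 transcripts per direction past the threshold that have groups that do not overlap, a mean of at least 5 TPM in the higher group and a symbol other than a predicted gene model. Where fewer pass, the next by smallest unadjusted p are added to make 5 per direction, 1 per gene, and are named as not passing. The rule further takes 16 genes of macrophage activation whatever their result, and up to 4 members with the smallest p, 1 transcript per gene, of each list past its threshold. Names taken from the authors' deposited comparison fall outside this rule and were chosen after their values were seen.

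Transcript lengths and classes came from GENCODE M21, matched by identifier. A length was found for 98.4% of the 1641 tested reference transcripts. Over all tested transcripts, which include assembled ones, it was 78.8%, so each check of length used the 1615 reference transcripts with a length. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

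The test was checked on simulated data with the means and spreads of the 2050 transcripts. Of 100 transcripts changed 8-fold, 71% were called, and of 100 changed 2-fold, 4% were called, with 2 false calls. In 20 further simulations no transcript was changed and only those at least 2-fold apart were kept. In these, 12.1% of the kept transcripts had an unadjusted p under 0.05, against 5.2% of unchanged transcripts without that selection.

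The alternatives planned before the data were examined were the replicate number as a block, leaving out each library in turn, rescaling the TPM by median ratios, quantile normalization, a pseudocount of 0.1, no filter on low values, a filter of at least 5 TPM in 3 libraries, limma without the trend, weights per library, a further threshold of 2-fold, and the estimated correlation in the list test. Chosen after seeing the data were an adjustment over 39400 transcripts, a term for sex-linked transcripts, a comparison of the libraries with Y-linked transcripts only, a correction for transcript length per library with its uncorrected companion, 1 transcript per gene in the list test, and the list test without Fn1.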

Results

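The transcriptomes of peritoneal macrophages were compared between WT and cKO mice after stimulation with IL-4 and IL-13, cytokines that drive alternative (M2) activation. FBXO38 is an F-box protein, the substrate-binding part of a ubiquitin ligase. There were 3 libraries per genotype, WT 1 to 3 and cKO 1 to 3. The deposited table lists 33539 transcripts that differed at least 2-fold in the authors' comparison, of which 13215 were listed as higher and 20324 as lower in cKO. WT 2 stood apart from the other libraries. Listed transcripts made up 6.57% of its TPM, against 2.01% to 3.79% in the other 5, and 4129 transcripts were above 0 in WT 2 alone. The sex-linked transcripts also split the libraries. Xist, expressed from the inactive X chromosome of females, was listed at 43.8 TPM in WT 2 and 3.83 TPM in WT 1 and at 0 in the other 4 libraries. The Y-linked Eif2s3y was listed at 51.2 TPM in WT 3 and at 35.6 to 45.1 TPM in the 3 cKO libraries. It was listed at 0 in WT 1 and WT 2. This split is uneven between the genotypes, so each comparison of all 3 WT with all 3 cKO libraries carries it.

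The targeted gene was examined first. Fbxo38 had 7 listed transcripts, 4 lower and 3 higher in cKO. The assembled transcript MSTRG.8674.6 was at 1.76, 3.22 and 3.34 TPM in WT 1 to 3 and at 0, 0.4 and 0 TPM in cKO 1 to 3. The reference transcript ENSMUST00000048688 was at 0.36, 3.78 and 0.78 TPM in WT and at 0.33, 0 and 0 TPM in cKO. In the other direction, MSTRG.8674.3 was listed at 0 in WT and in cKO 1 but at 5.4 and 2.27 TPM in cKO 2 and cKO 3. The 7 listed transcripts together reached 11.0 ± 1.95 TPM in WT and 7.04 ± 1.77 TPM in cKO (SD, n = 3 each), and cKO 2, at 9.08 TPM, overlapped WT 1, at 8.79 TPM. This sum differed by -0.59 ± 0.49 (SE) on the log2(TPM + 1) scale, with an exact permutation p of 0.2. None of the 4 tested Fbxo38 transcripts passed the adjusted threshold, the lowest limma adjusted p being 0.134 for MSTRG.8674.6. The deleted exons are not given in the sources used here, so it is not known which of these transcripts report on the deletion. Transcripts of Fbxo38 outside the table were not analysed here.

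**Figure D1:**
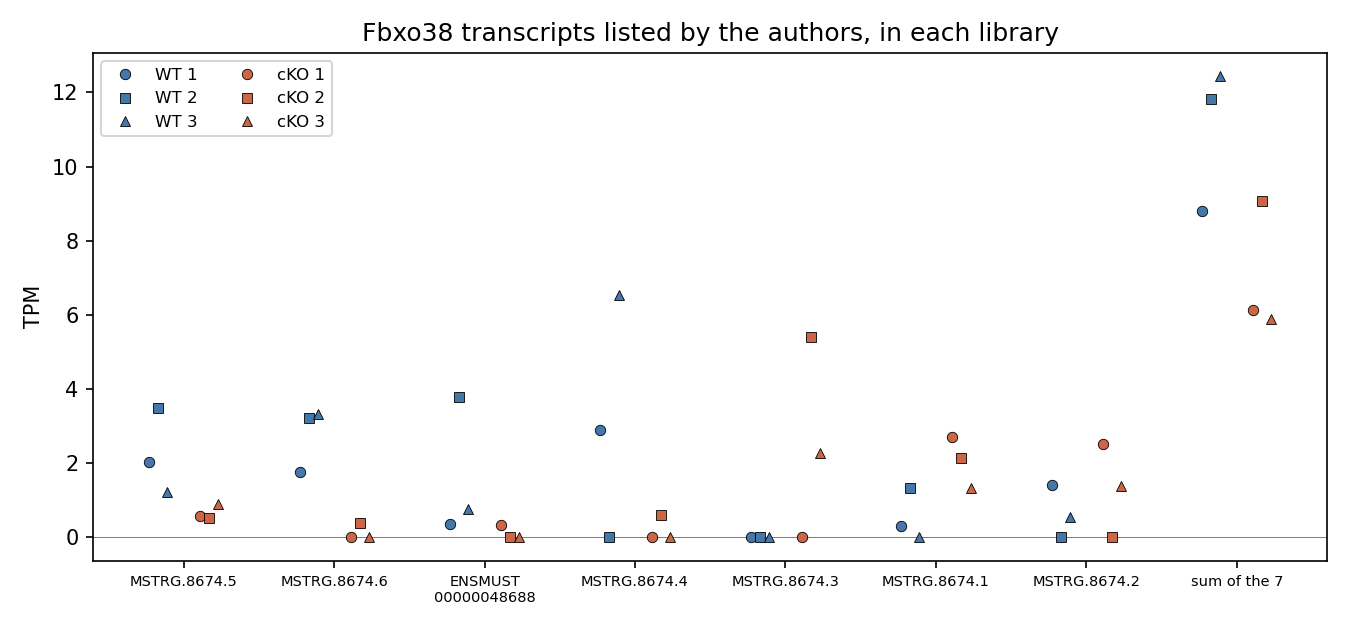
TPM of the 7 listed Fbxo38 transcripts and of their sum (y axis) in each of the 3 WT (blue) and 3 cKO (orange) libraries, with 1 point per library. MSTRG.8674.6 was at 1.76 TPM or more in WT and at 0.4 TPM or less in cKO, whereas the sums of WT 1 (8.79 TPM) and cKO 2 (9.08 TPM) overlapped.

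In the authors' deposited table, the most abundant transcript called at an adjusted p under 0.05 belonged to the lysozyme gene Lyz1. Its log2 fold change there was 2.60, with an adjusted p of 1.58e-07. Lyz1 ENSMUST00000092162 was at 72.0, 38.2 and 63.7 TPM in WT and at 312, 224 and 283 TPM in cKO. Its near-identical copy Lyz2 has no transcript among those listed and was not analysed here. Gata6, the transcription factor of resident large peritoneal macrophages, was lower in cKO in the authors' deposited table, with a log2 fold change of -2.08 and an adjusted p of 0.0267. Its TPM were 2.57, 9.27 and 5.1 in WT and 0.89, 1.74 and 0.52 in cKO. Transcripts of Cdh2, which encodes N-cadherin, of the imprinted noncoding RNA H19, of the basement membrane gene Nid1 and of the ubiquitin ligase gene Nedd4 were also lower in the authors' deposited table, with log2 fold changes of -2.46, -3.02, -2.07 and -2.14. As for Gata6, WT 2 was the highest library for each of these transcripts. H19 was at 1.59, 6.22 and 1.72 TPM in WT 1 to 3, and Nedd4 at 6.53, 34.7 and 16.5 TPM. In each, the lowest WT value still lay above the highest cKO value. Tmem59, a membrane protein gene, and the cell cycle inhibitor gene Cdkn1c each had a transcript that was higher, with log2 fold changes of 1.43 and 1.80 in the authors' deposited table. The Tmem59 transcript is annotated as a retained intron and was at 30.6 ± 12.0 TPM in WT and 62.0 ± 7.99 TPM in cKO (SD, n = 3 each).

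The authors' deposited table holds 90 transcripts at an adjusted p under 0.05, 33 higher and 57 lower in cKO. Of these, 62 were listed at 0 in all 3 libraries of a genotype, 20 in WT and 42 in cKO. The median of their highest TPM in any library was 1.75. For 64 of the 90, another transcript of the same gene was listed in the opposite direction. Opposite directions were at the level of chance in the table, at 47.5% of genes with exactly 2 listed transcripts, against 47.8% if directions were independent. Sirt3, a mitochondrial deacetylase gene, had 1 called transcript in each direction. Sirt3 MSTRG.17105.5 was at 1.91, 1.05 and 1.63 TPM in WT and listed at 0 in cKO, and Sirt3 ENSMUST00000147331 was listed at 0 in WT and at 1.16, 2.62 and 1.19 TPM in cKO. Fbxo7, an F-box gene, likewise had a called transcript in each direction. All genes named from this comparison were chosen after their values were seen.

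**Figure D2:**
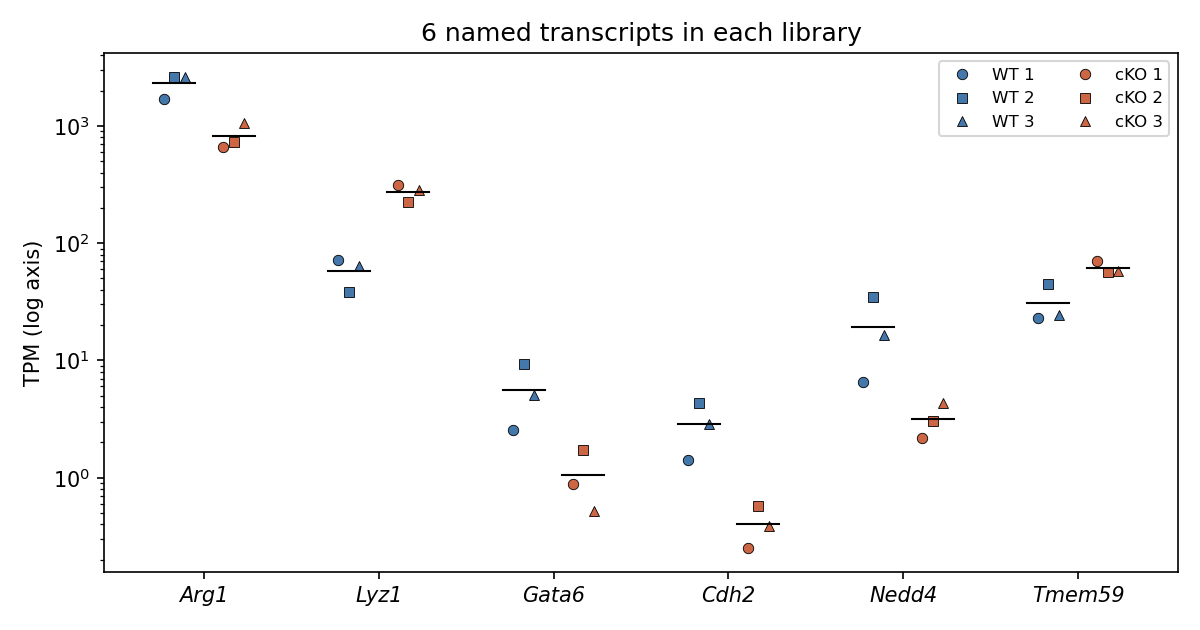
TPM (y axis, log scale) of 1 transcript each of Arg1, Lyz1, Gata6, Cdh2, Nedd4 and Tmem59 in the 3 WT (blue) and 3 cKO (orange) libraries, with 1 point per library and a line at the group mean. Lyz1 was at 72.0 TPM or less in WT and at 224 TPM or more in cKO, and Arg1 was at 1690 TPM or more in WT and at 1067 TPM or less in cKO.

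In the limma test of the 2050 transcripts with at least 1 TPM in 3 libraries, 0 transcripts passed the adjusted threshold, 0 higher and 0 lower in cKO, and the lowest adjusted p was 0.0651. At an unadjusted p under 0.05 there were 472 transcripts, 125 higher and 347 lower in cKO. That is 23% of those tested, against 12.1% in simulations without any change that kept only transcripts at least 2-fold apart. The simulated transcripts were independent of each other and were kept by their TPM ratio, not by the authors' fold change. These shares therefore do not show an excess beyond the selection and the scale. By the authors' fold change, 1021 of the tested transcripts were higher and 1029 lower in cKO. The groups did not overlap for 759 transcripts, or 37.0%, where chance gives 10% without a selection. Of the 90 transcripts called in the authors' deposited table, 31 were among those tested here. The log2 ratio of mean TPM minus the log2 fold change in the authors' deposited table had a median of -0.38 over the 2026 tested transcripts above 0 in both groups, so values on the TPM scale are shifted toward lower in cKO.

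The transcripts with the smallest p that met the other criteria did not pass the limma test. Among those lower in cKO were Ndufb5, a subunit of respiratory complex I, the chromatin protein gene Hmgb1, the mitochondrial fusion gene Mfn1, the Polycomb gene Eed and Cipc, which encodes a partner of CLOCK. The Ndufb5 transcript was at 14.4, 32.8 and 11.5 TPM in WT and at 0.56, 0 and 0 TPM in cKO, a log2 fold change of -4.01 ± 0.53 (SE). The log2 fold changes of the other 4 were between -3.31 for Cipc and -2.49 for Mfn1. Among those higher were transcripts of Tkt, the transketolase of the pentose phosphate pathway, of the calpain subunit gene Capns1, of Eed, of the ubiquitin ligase gene Trim41 and of Hax1, an inhibitor of apoptosis. The Tkt transcript, a retained intron, was listed at 0 in WT and at 10.2, 5.66 and 4.69 TPM in cKO. The Hax1 transcript was at 5.36, 0 and 0 TPM in WT and at 29.4, 11.8 and 20.9 TPM in cKO, a log2 fold change of 3.46 ± 0.81 (SE). For Eed the direction depended on the transcript, with ENSMUST00000107234 at -2.51 and ENSMUST00000238981 at 2.38. The transcripts of Hmgb1, Mfn1 and Capns1 are annotated as retained introns. In the authors' deposited table some of these transcripts were called. The adjusted p there was 1.81e-10 for Tkt, 1.07e-06 for Ndufb5, 2.73e-05 for Capns1 and 7.46e-05 for Eed ENSMUST00000238981. The others named in this paragraph were not called there.

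Arg1, which hydrolyses arginine and is the standard marker of alternative activation in mouse macrophages, had 3 listed transcripts, each with a lower mean in cKO. Its main transcript ENSMUST00000020161 was at 2308 ± 535 TPM in WT and 816 ± 220 TPM in cKO (SD, n = 3 each), 2.83 times higher in WT, with no overlap between the groups. The log2 fold change was -1.50 ± 0.49 (SE) and did not pass the limma test, with an adjusted p of 0.209. In the authors' deposited table the log2 fold change of this Arg1 transcript was -1.09, with an adjusted p of 0.0854. The other listed Arg1 transcripts, ENSMUST00000218260 and ENSMUST00000220186, are annotated as retained introns. The lectin gene Mgl2 had 2 listed transcripts, the tested ENSMUST00000132645 being at 0, 1.79 and 2.8 TPM in WT and at 0, 1.17 and 0 TPM in cKO. The single listed transcript of Retnla, a secreted protein gene of alternative activation, was at 38.1 TPM in WT 2 and 139 TPM in cKO 2 and listed at 0 in the other 4 libraries. The listed transcripts of Pdcd1lg2, Nos2 and Il6 stayed under the filter, at 1.17 TPM or less in each library. Chil3, Mrc1, Ccl17, Ccl22, Ccl24, Irf4, Cd274, Il1b, Tnf and Lyz2 have no transcript among those listed and were not analysed here.

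The list of genes induced by IL-4 and IL-13 was lower in cKO in the list test, with 24 of 26 tested transcripts lower, a median log2 fold change of -1.08 and an adjusted p of 0.00825 by limma's camera. The call was not held with an estimated correlation, adjusted p = 0.753. No member passed, also when adjusted over the list alone. The 26 transcripts came from 12 genes, and 10 of them were isoforms of the matrix gene Fn1. Without Fn1 the median was -0.96 and the adjusted p 0.0329, and with 1 transcript per gene the adjusted p was 0.158. Lower members included a transcript of the receptor gene Il4ra at -1.21 and of the kinase gene Matk at -1.29. The Il4ra transcript is annotated as subject to nonsense-mediated decay and was at 3.37 TPM or less in each library. A transcript of the transcription factor gene Egr2 was higher, at 1.48. The level of this list was highest in WT 2, at 1.45 above the mean of the libraries on the log2 scale, and WT 1, at -0.50, lay within the cKO range of -0.67 to -0.36. Without WT 2 the median was -0.64 and the adjusted p 0.069.

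Matrix genes and markers of mesothelial cells and fibroblasts, cell types of the peritoneal lining, were lower in cKO together with that list. The lists overlap, as the 10 Fn1 transcripts are also in the matrix list, and 4 collagen transcripts, of Col1a1, Col1a2 and Col3a1, are in the matrix and the mesothelial list. Of 27 tested transcripts of the matrix and TGF-beta list, 26 were lower, with a median log2 fold change of -1.29 and an adjusted p of 0.00342 by camera. All 15 tested transcripts of the mesothelial and fibroblast list were lower, with a median of -1.34 and an adjusted p of 0.00773. Neither call was held with an estimated correlation, adjusted p = 0.753 for each. No member of either list passed, also when adjusted over the list alone. Matrix members were the crosslinking enzyme gene Lox at -1.47, Thbs1 at -1.51, Tgfbi at -1.33 and the protease gene Mmp2 at -1.16. Mesothelial and fibroblast members were the growth factor receptor gene Pdgfra at -1.43, the complement gene C3 at -1.38, the mesothelial transcription factor gene Wt1 at -1.23 and the keratin gene Krt8 at -1.34. A collagen transcript of these lists, from Col1a2, was at 16.6, 146 and 50.0 TPM in WT and at 5.32, 18.3 and 15.2 TPM in cKO. The level of the mesothelial list was 1.83 in WT 2 and 0.55 in WT 3, while WT 1, at -0.33, lay within the cKO range of -1.35 to -0.32. Without WT 2 the median of the matrix list was -0.69 and that of the mesothelial list -0.84, each with an adjusted p of 0.0398.

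**Figure D3:**
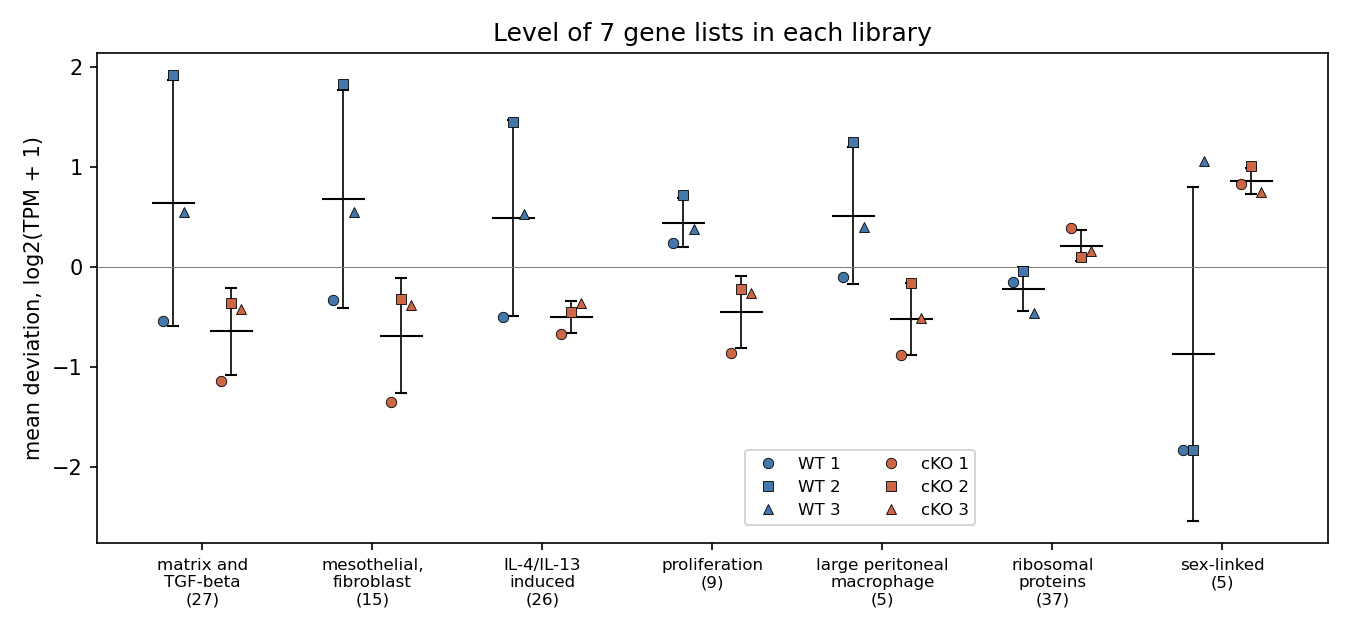
Level of 7 gene lists in each library (y axis), as the mean over the tested transcripts of the deviation from the transcript's mean over the 6 libraries, in log2(TPM + 1); points are libraries, lines and bars are means and SD (n = 3), and the number of transcripts is in parentheses. For the matrix, mesothelial and IL-4/IL-13 lists WT 2 was highest and WT 1 lay within the cKO range; for the proliferation and ribosomal lists the groups did not overlap.

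Proliferation genes were lower in cKO, with 8 of 9 tested transcripts lower, a median log2 fold change of -1.10 and an adjusted p of 0.0239 by camera. The call was lost with an estimated correlation, adjusted p = 0.753, without WT 1 (0.0568) and without cKO 1 (0.0694). It passed in 11 of 20 alternative settings, and with no filter on low values the median was -0.17 and the adjusted p 0.13. Members were Prc1 at -1.15, the topoisomerase gene Top2a at -1.37, Cdc20, an activator of the anaphase-promoting complex, at -1.35, and the kinesin gene Kif11 at -0.92. The Cdc20 transcript was at 10.1 ± 2.23 TPM in WT and 3.57 ± 1.81 TPM in cKO (SD, n = 3 each). Ribosomal protein transcripts were higher in cKO, with 29 of 37 higher, a median of 0.66 and an adjusted p of 0.0148 by camera. This call was lost with an estimated correlation, adjusted p = 0.753, without WT 3 (0.0515) and without cKO 1 (0.0694). Transcripts of Rpl23 and Rpl28 were listed at 0 in WT and at 3.74 and 1.34 TPM on average in cKO, Rps18 was at 1.44 on the log2 scale, and a transcript of Rps7 was listed at 0 in cKO. When adjusted over the list alone, 3 of the 37 ribosomal transcripts passed. They were those of Rpl23 and Rpl28, higher in cKO, and that of Rps7, lower in cKO. None of them was called in the authors' deposited table. The Rps7 transcript, a retained intron, was at only 1.25 TPM on average in WT. The sex-linked list was higher in cKO, with 5 of 5 transcripts higher and an adjusted p of 0.0213, again lost with an estimated correlation, adjusted p = 0.753. The call was also lost without WT 1 (0.0827), without WT 2 (0.14), without cKO 2 (0.0656) and with library weights (0.266), and the median was -0.12 in the libraries with Y-linked transcripts. WT 1 and WT 2 had 0 TPM of Eif2s3y and Uty. The level of the list was -1.83 in WT 1 and in WT 2. In WT 3 it was 1.06, above the cKO range of 0.75 to 1.01. The difference of this list therefore came from WT 1 and WT 2 and did not follow the genotype. The members of the list were Ddx3y at 1.18, Eif2s3y at 3.41 and Uty at 0.82. No proliferation or sex-linked member passed when adjusted over the list alone.

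Markers of resident large peritoneal macrophages had 5 tested transcripts, each lower in cKO, with a median of -1.09, and did not pass (adjusted p = 0.0944 by camera). The level of this list was 1.25 in WT 2, 0.40 in WT 3 and -0.10 in WT 1, against -0.88 to -0.16 in cKO, with WT 2 highest as for the matrix and mesothelial lists. One of its transcripts, of Thbs1, is also in the matrix list. The others included Gata6, at -1.61, Adgre1, which encodes F4/80, at -1.09, and the retinoic acid receptor gene Rarb, at -0.77. LXR targets had 5 of 5 transcripts lower and an adjusted p of 0.149, and the MAPK feedback list 6 of 7 lower and an adjusted p of 0.347. The other 11 tested lists did not pass either, with adjusted p of 0.626 or more. These were the lists of general myeloid genes, lysosome and phagocytosis, glycolysis, proteasome, oxidative phosphorylation, interferon-stimulated genes, SCF ligase subunits, NF-kB and classical activation, the unfolded protein response, checkpoint and suppressive mediators, and MHC class I. When adjusted over the list alone, 1 transcript each passed for general myeloid genes (Lyz1, at 2.25), lysosome and phagocytosis (Ctsh, at -1.32), oxidative phosphorylation (Ndufb5), MHC class I (H2-M3, at -2.13) and SCF subunits, and 0 in the others. The SCF member was Fbxo38 MSTRG.8674.6, of the targeted gene, which gave 4 of the 6 tested transcripts of that list. In the authors' deposited table the adjusted p was 1.58e-07 for this Lyz1 transcript and 1.07e-06 for that of Ndufb5. There it was 0.0937 for Ctsh, 0.947 for H2-M3 and 0.725 for Fbxo38 MSTRG.8674.6. By fry, which asks whether the members of a list move on balance in 1 direction and compares them with no other transcripts, 0 of the 20 lists passed. By its test for changes in either direction 10 passed, with adjusted p from 0.000656 for oxidative phosphorylation to 0.0464 for MHC class I, in a table selected for differences between the groups. The remaining 17 lists had fewer than 5 tested transcripts and were not tested, among them MHC class II, fatty acid oxidation, cholesterol synthesis, p53 targets and NRF2 targets.

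The direction of a difference followed the length of the transcript. Across the 1615 tested reference transcripts with a length, which are not independent replicates, the log2 fold change had a Spearman rho of -0.37 with length. In the shortest quartile, up to 524 nt, 67.3% were higher in cKO, and in the longest, from 2320 nt, 14.4% were. The median length was 4061 nt in the matrix list, 3622 nt in the mesothelial list, 2778 nt in the IL-4/IL-13 list and 464 nt in the ribosomal list, against 810 nt over all 1615. A correction for length in each library moved the median of the matrix list from -1.25 to -0.57 (adjusted p = 0.0486) and that of the mesothelial list from -1.35 to -0.64 (adjusted p = 0.0616). The IL-4/IL-13 list went from -1.08 to -0.40 and the proliferation list from -1.10 to -0.44, each with an adjusted p of 0.207. The ribosomal list went from 0.66 to 0.52, with an adjusted p of 0.283.

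**Figure D4:**
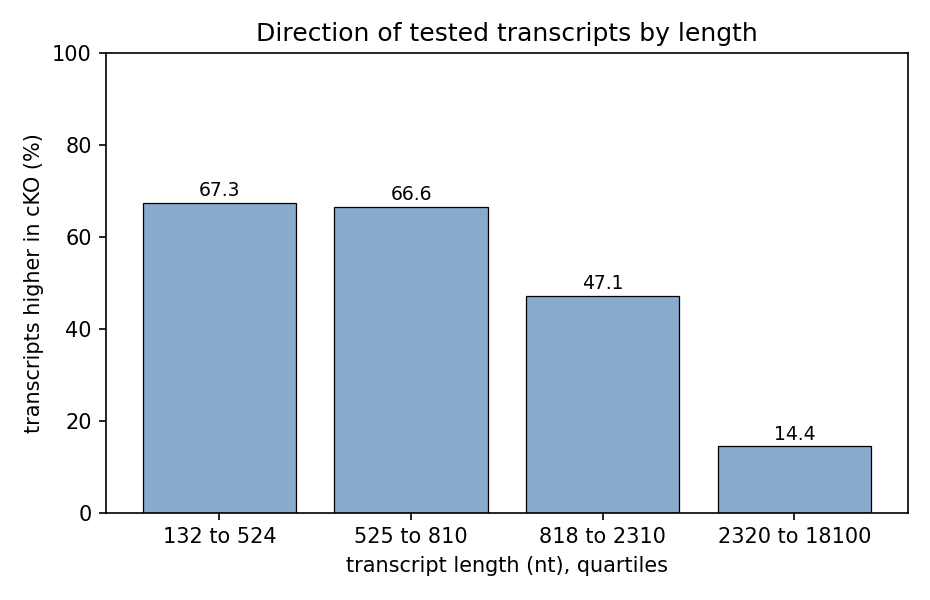
Percent of tested reference transcripts that were higher in cKO (y axis), by quartile of transcript length in nt (x axis, 1615 transcripts in all). The share was 67.3% in the shortest quartile and 14.4% in the longest.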

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

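The term for and the restriction by sex-linked transcripts, the length correction, the adjustment over 39400 transcripts, 1 transcript per gene and the list test without Fn1 were chosen after seeing the data. Under limma, 0 transcripts passed in the main setting, and 0 also with the replicate block, a pseudocount of 0.1, no filter, the filter of 5 TPM, no trend, the 2-fold threshold, the wider adjustment and both settings for sex-linked transcripts. With size factors 1 passed (0 higher, 1 lower, Gm42959). With quantile normalization and with library weights 3 passed in each, 1 higher (Tkt) and 2 lower (Ndufb5, Gm42959). After the length correction 4 passed, 2 higher (Tkt, Pja2) and 2 lower (Ndufb5, Gm42959). Leaving out 1 library gave 0 to 4 transcripts, 0 higher and 0 to 4 lower. The 4, with Cipc among them, passed without cKO 2. Gm42959 and Pja2 were chosen after their values were seen. The cause was not tested.

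The summed Fbxo38 log2 fold change was -0.76 to -0.19 over the alternatives and passed in none. The number of lists past the threshold was 6. It was 0 with an estimated correlation, 3 with the term for sex-linked transcripts, 3 with 1 transcript per gene, 1 after the length correction, and 4 to 6 without 1 library. With no filter it was 5. The IL-4/IL-13 list (-0.30, adjusted p = 0.0806 by camera) and the proliferation list (-0.17, adjusted p = 0.13) were lost and oxidative phosphorylation was gained (adjusted p = 0.0273). The lists that kept their calls there also had medians nearer to no change. These were -0.70 for the matrix, -0.51 for the mesothelial, 0.30 for the ribosomal and 0.15 for the sex-linked list. With library weights 4 lists passed, the proliferation list (adjusted p = 0.0508) and the sex-linked list (adjusted p = 0.266) being lost. The proliferation list passed in 11 of 20 settings. The proliferation list lost its call without WT 1 or cKO 1, the IL-4/IL-13 list without WT 2, the ribosomal list without WT 3 or cKO 1, and the sex-linked list without WT 1, WT 2 or cKO 2. The matrix and mesothelial lists kept theirs without any library. In both settings for sex-linked transcripts the WT side rests on WT 3 alone, so they are 1 comparison with different error estimates. The sex-linked list reversed to -0.12 with the term and with the libraries restricted, as did Uty at -0.12 and Eif2s3y at -0.39. Fbxo38 MSTRG.8674.2 was at 0 to 0.91 without 1 library, from 0.39, with the 0 without cKO 1. Of the list medians, 92 kept direction and side of the threshold, 27 lost the threshold and 2 reversed. Of the named transcripts, 634 values kept both, 7 newly passed and 5 reversed. Rescaling by size factors moved the median of all tested transcripts by 0.28, from -0.39 to -0.10, and quantile normalization by 0.07. With size factors the list medians were -0.67 for the IL-4/IL-13, -0.90 for the matrix, -0.93 for the mesothelial and -0.74 for the proliferation list. They were 0.95 for the ribosomal and 1.74 for the sex-linked list, and 6 lists passed. The main Arg1 transcript was at -1.06 in that setting.

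Pairing by replicate number was not visible in the values. The correlations of same-numbered deviations from the group means were 0.13, -0.14 and -0.11, and those of other pairs ranged from -0.19 to 0.23. With 3 libraries per group they cannot show which libraries came from littermates. With the replicate block the count stayed at 0, with 499 transcripts at an unadjusted p under 0.05 against 472, and 6 lists passed. Depth is unknown, so no limit from depth is given.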

Other observations

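All tests of explanations in this part were chosen after the results were seen. A second deposited sheet lists 17 transcripts, all with a negative log2 fold change, among them Mapk3, Mapk9, Mapk8ip3, Thbs1, Wnt4, Tgfb3 and Cdh2. Such a list, chosen on these samples, is not independent evidence of its direction. An adjusted p under 0.05 is given for 3 of the 17 in the authors' deposited table, namely Cdh2, Mapk8ip3 and Cdon. For 11 of them the lowest WT value lay above the highest cKO value, and 6 were listed at 0 in all cKO libraries. Mapk9 ENSMUST00000043321 was at 0.68, 1.09 and 1.76 TPM in WT and at 0.18, 0.24 and 0 TPM in cKO. The MAPK feedback list fixed before the data were examined had 6 of 7 tested transcripts lower, Egr1 at -0.85 and Fosl2 at -0.94 among them, and did not pass (adjusted p = 0.347 by limma's camera).

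Several other genes of macrophage function had transcripts with large differences that did not pass by limma, chosen here after their values were seen. Mmp12, the macrophage elastase gene, was at 56.5, 36.6 and 44.0 TPM in WT and at 402, 57.7 and 613 TPM in cKO, so that cKO 2 was near WT. Tyrobp, which encodes the signalling adaptor DAP12, followed the same libraries, at 365, 175 and 252 TPM in WT and 896, 224 and 848 TPM in cKO. A Ctsh transcript, of the protease cathepsin H, was at 2.14, 1.16 and 1.28 TPM in WT and listed at 0 in cKO. Among markers of other immune cells few transcripts were listed with at least 1 TPM in 3 libraries: 0 for B cells, neutrophils, eosinophils and mast cells or basophils, 1 for T and NK cells and 2 for dendritic cells. Monocyte-derived small peritoneal macrophages and endothelial cells had 1 each, and red cells or platelets 0. These lists were too small for the list test. B cell markers had 33 listed transcripts, 15 higher and 18 lower in cKO, all under that filter. The table holds only transcripts at least 2-fold apart between the groups. These counts therefore do not show whether such cells were present.

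In the limma test 0 transcripts passed with the real groups, and the highest count among the other 9 of the 10 splits of the 6 libraries was 15, when WT 1, WT 3 and cKO 2 were set against the rest. The split with 15 calls, which had 138 transcripts at an unadjusted p under 0.05, may point to a structure of the libraries that does not follow the groups, which was not tested. With 10 splits there are too few for a share under 0.05. The listed transcripts had been selected on the real split, where 472 had an unadjusted p under 0.05, against at most 195 in the others.

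For the matrix and mesothelial transcripts, lower in cKO as a group, a candidate explanation is a differing share of mesothelial cells or fibroblasts. Members of the mesothelial list moved together after the group means were taken out, with a correlation of 0.84. Such a correlation was also 0.54 in the IL-4/IL-13 list, which shares no transcript with the mesothelial list. However, 10 of its 26 transcripts are Fn1 isoforms that are also in the matrix list, so it is no separate comparison. The correlation was 0.34 in the proliferation list, which shares no transcript with the matrix or the mesothelial list, and 0.07 in the ribosomal list. Other differences between libraries can also move members together, so the correlation does not by itself set a cell share apart. WT 2 alone leaves the matrix list at -0.69 when it is left out, but then WT 3 is the single WT library above the cKO range, so 1 library cannot be separated from the genotype. The length trend as the whole cause stays open, since the correction moved the median of the mesothelial list from -1.35 (SD 0.39 over its members) to -0.64 (SD 0.42). With that smaller median, at a similar spread, its call ended (adjusted p = 0.0616 by limma's camera), while the matrix list, with 24 transcripts against 12, went from -1.25 (SD 0.41) to -0.57 (SD 0.37) and stayed narrowly past the threshold (adjusted p = 0.0486); all 24 and all 12 members were still lower. The difference in sex-linked transcripts also stays open, only because WT is WT 3 alone in the libraries with Y-linked transcripts, where the median was -1.24 for the matrix list (adjusted p = 0.00173) and -1.37 for the mesothelial list (adjusted p = 0.0103), both past the threshold; with a term for these transcripts the medians were the same and the adjusted p 0.0361 and 0.0614.

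The length trend was not particular to the TPM scale. The log2 fold change in the authors' deposited table, from DESeq2, had a rho of -0.36 with length. Both fold changes come from the same libraries, in rows selected by the authors' fold change. Their likeness therefore says nothing on the quantification of transcripts, which was not tested as a source. RNA or library quality that differs from library to library may contribute. The rho of a library's deviation with length ranged over 0.30 in WT, from 0.05 to 0.35, and was -0.40, -0.09 and -0.30 in cKO. The groups did not overlap, so quality and genotype cannot be told apart with 3 libraries each. No value of RNA integrity per library was used here.

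For Lyz1, higher in cKO in each library, reads shared with Lyz2 remain possible, since 0 transcripts of Lyz2 are listed and its level could not be set beside that of Lyz1. A hypothesis not tested here is that a Cre allele inserted at Lyz2, as used in many myeloid deletions, may alter lysozyme transcripts; the Cre line is not given in the sources used here. Reads of Lyz1 and Lyz2 set apart, in mice with the Cre allele and intact Fbxo38, would decide it. Strain DNA around the lysozyme genes also stays open, since 3.4% of the other calls in the authors' deposited table lay on their chromosome, against 4.3% of listed transcripts, a share that says nothing on Lyz1 itself.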
